A study of Mus musculus with 48 samples.

How the data were processed

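Polyadenylated RNA was sequenced from 4 brain regions of 16-week-old female and male mice under 2 genotype labels, with 3 libraries for each of the 16 combinations. Per the labels, the authors aligned reads with HISAT2 2.0.5 to mm39, and DESeq2 is named for their differential expression. The deposited table holds raw counts per gene for 56748 genes and all 48 libraries, of which 39254 genes had a count above 0 in any library. It also gives a gene length in bases per the file headers, which was not used in any test. The counting tool, its strand setting, the annotation release and the treatment of reads that map to several places are not stated. The labels do not say whether libraries that share a replicate number came from the same animal. The extraction protocol in the labels speaks of liver lysates although the source is brain, and liver transcripts were therefore checked. Columns were assigned to samples by the column name given in each sample's description, and no sample was left out of the comparisons.

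Library totals ranged from 14.56 M to 25.86 M counts (M for mega). In that unit they spanned 14.92 to 25.86 (KO) and 15.07 to 19.23 (WT) in the cerebellum, 15.81 to 19.78 and 15.44 to 18.52 in the dorsal hippocampus, 14.56 to 20.78 and 15.31 to 17.98 in the medial prefrontal cortex, and 15.64 to 20.94 and 15.4 to 16.07 in the ventral hippocampus. Intervals on pooled ratios are exact 95% intervals that cover counting error only. The square root of the dispersion stored with the fit, taken from its first value, was 0.2, 0.0893, 0.0715 and 0.145 in these regions. Among 48 pairs of libraries within groups, none was a copy of another (lowest chi-square per degree of freedom 3.73).

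Counts were analysed in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM factors). Genes were filtered with filterByExpr (minimum count 10, minimum total 15) and p-values were adjusted by Benjamini and Hochberg over the genes tested, with calls at an adjusted p under 0.05. Each region was fitted apart, with a mean for each of its 4 sex by genotype groups. The contrasts were KO against WT averaged over the sexes and within each sex, the sex by genotype difference, and female against male averaged over genotype. Dorsal against ventral hippocampus was tested over 24 libraries, and an F test over all 48 asked whether the KO against WT difference varied between regions. CPM values are on TMM-scaled library sizes, and errors are the SD between libraries or the SE of the fitted log2 change. A set of 47 gene lists written from general knowledge, and the genes within 5 Mb of Cyp2e1, were tested with camera of limma 3.58.1 at its preset correlation and with an estimated correlation, and with fry. List p-values were adjusted over all lists and regions together. Calls adjusted over the list alone are given beside those over all genes where stated.

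Groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Cyp2e1, up to 12 genes each way called with the same sign in all 4 regions, and per region 5 genes each way with the smallest p, the same sign in both sexes and a mean of at least 10 counts. It also named the 4 members with the smallest p of lists that were called or had 2 called members, the 3 smallest p for sex by genotype, 4 autosomal genes each way for sex, 6 genes for the difference between regions, 8 each way for dorsal against ventral with at least 50 counts, and up to 8 genes near Cyp2e1. Genes with placeholder names were counted but not named unless stated, and some genes named by the rule are not reported here. Alternatives were DESeq2 1.42.0, size factors of the DESeq2 type, no low-count filter, a stricter filter (1 CPM in 6 libraries), the replicate number as a block, all 48 libraries in one model, only the libraries of the sex tested, and leaving out each library in turn. Added after seeing the data were a marker mean as a covariate (cerebellar granule list in cerebellum and hippocampus, striatal list in prefrontal cortex), the removal of 9 libraries doubted for these markers, and the test between regions without the cerebellum.

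The procedure was tested on simulated data with 200 changed genes. Each gene was drawn independently, so the simulation lacked shifts shared by many genes between libraries. The rates below need not hold where such shifts exist, and they do not measure false calls in the real data. For KO against WT it recovered 31.3%, 52.2%, 65.7% and 43.3% of 1.5-fold changes in cerebellum, dorsal hippocampus, medial prefrontal cortex and ventral hippocampus, 65.7%, 70.1%, 85.1% and 71.6% of 2-fold changes, and 89.4%, 97%, 100% and 95.5% of 4-fold changes. For sex by genotype it recovered 14.9%, 47.8%, 58.2% and 20.9% of 2-fold differences.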

Results

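Messenger RNA was sequenced from dissected brain regions of 16-week-old mice of both sexes. The mice carried either of 2 genotype labels, 129/Sv-Cyp2e1tm1Gonz/J, a line with a targeted Cyp2e1 gene (KO), or 129S1/SvImJ (WT). The 48 libraries fell into 16 groups of 3, formed by sex, genotype label and the 4 regions cerebellum, dorsal hippocampus, medial prefrontal cortex and ventral hippocampus. Each library held between 14.56 M and 25.86 M counts (M for mega), with a median of 16.57 M. Between 23396 and 26923 of the 56748 genes listed had a count above 0 in a library. Mitochondrially encoded transcripts took 2.72% to 4.29% of a library, and its 10 most abundant genes took 3.99% to 5.51%. The question the labels pose is how the 2 genotype labels differ in each region and sex. Positions are those of the deposited table, on mm39.

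Cyp2e1 (ENSMUSG00000025479, chromosome 7, 140343652 to 140354900), a cytochrome P450 that oxidises ethanol and other small molecules, was higher in the libraries labelled KO in every region. This direction goes against the label, since the targeted line carries the disrupted gene. In the cerebellum its level was 4.07 ± 0.637 CPM (counts per M of the scaled library total) under the KO label and 0.199 ± 0.147 under the WT label (SD, n = 6 each). The corresponding levels were 4.16 ± 0.898 and 0.128 ± 0.113 in the dorsal hippocampus, 3.06 ± 0.662 and 0.0735 ± 0.102 in the medial prefrontal cortex, and 4.69 ± 0.976 and 0.151 ± 0.130 in the ventral hippocampus (n = 6 each). All 24 libraries labelled KO held 34 to 111 Cyp2e1 counts, and all 24 labelled WT held 0 to 8, with 5 of these at 0. Pooled over libraries, the ratio of KO to WT was 20.2 in the cerebellum (95% exact interval 12.9 to 33.3), 33.0 in the dorsal hippocampus (19.1 to 62.4), 42.9 in the medial prefrontal cortex (20.6 to 108) and 31.4 in the ventral hippocampus (18.5 to 57.9). The edgeR test gave adjusted p = 0.00012, 1.3e-06, 2.7e-06 and 4.9e-06 in that order. Syce1, a neighbouring gene of the synaptonemal complex, had ratios of 0.391 (0.252 to 0.595), 0.897 (0.531 to 1.51), 0.952 (0.528 to 1.72) and 1.15 (0.738 to 1.8) in the same regions. The counts do not resolve which exons the Cyp2e1 reads came from. All directions in the following paragraphs are those of the labels as deposited, so they reverse if the labels are exchanged.

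**Figure D1:**
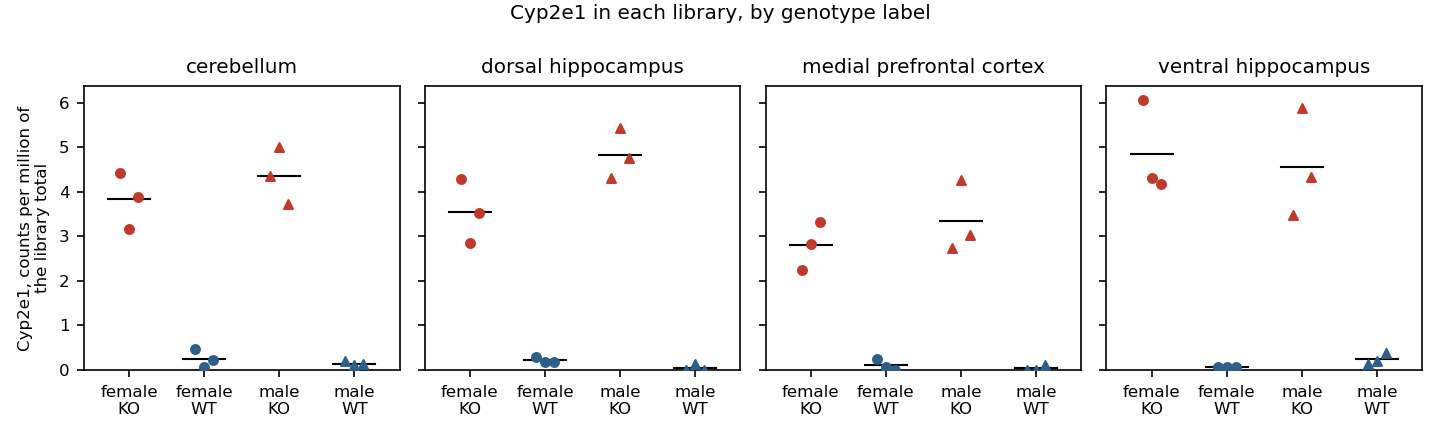
Cyp2e1 in CPM on the unscaled library total (vertical axis) in each of the 48 libraries, by region, sex and genotype label. Points are libraries (3 per group) and the bar is the group mean. Libraries labelled KO lie between 2.24 and 6.07, and libraries labelled WT between 0 and 0.461.

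Genotype labels were compared in each region with the sexes averaged. Genes that differed with the same sign in all 4 regions, beside Cyp2e1, are given first. Aff1 (a subunit of the super elongation complex), Klhl8, Nudt9 (an ADP-ribose pyrophosphatase), Ttll12 and Hsd17b11 (a lipid droplet dehydrogenase) were higher under the KO label. Glo1 (glyoxalase 1, which detoxifies methylglyoxal) was lower. Klhl8 stood at 74.7 ± 2.27 against 38.9 ± 2.13 CPM in the dorsal hippocampus (SD, n = 6 each; log2 change 0.94, SE 0.05, adjusted p = 1.7e-07). Nudt9 stood at 74.0 ± 2.51 against 38.8 ± 2.48 CPM in the medial prefrontal cortex (log2 change 0.93, SE 0.04, adjusted p = 2.6e-09). Glo1 stood at 86.4 ± 5.90 against 213 ± 26.3 CPM in the cerebellum (log2 change -1.30, SE 0.08, adjusted p = 3.6e-05), and its log2 change was -1.22, -1.17 and -1.21 in the dorsal hippocampus, medial prefrontal cortex and ventral hippocampus. In cerebellum, dorsal hippocampus, medial prefrontal cortex and ventral hippocampus Aff1 changed by 1.32, 1.11, 1.07 and 1.00 on the log2 scale, and Ttll12 by 0.76, 0.99, 1.03 and 0.88. Hsd17b11 changed by 0.39, 0.92, 0.88 and 0.79, and its cerebellar value combined 0.71 in females with 0.07 in males. Of 16236 genes tested in every region, 13 were called in all 4, among them Cyp2e1, the genes above and 4 genes with placeholder names. Chosen after its values were seen, the long noncoding RNA Gm10503 had WT to KO ratios of 1320 (95% exact interval 237 to 52300), 352 (171 to 877), 806 (223 to 6660) and 1950 (350 to 77100) in cerebellum, dorsal hippocampus, medial prefrontal cortex and ventral hippocampus. Dorsal hippocampus and medial prefrontal cortex shared 14 genes higher under the KO label, where calls independent between regions would share 0.0554, and medial prefrontal cortex and ventral hippocampus shared 8, where such calls would share 0.0143. If the regions came from the same mice, which the labels do not state, more sharing than this arises without a genotype effect. Without 9 libraries doubted for their marker levels, 8 of the 13 genes were still called in all 4 regions, and Aff1 and Hsd17b11 were not among them. With the replicate number added as a block, 9 of the 13 were still called in all 4.

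**Figure D2:**
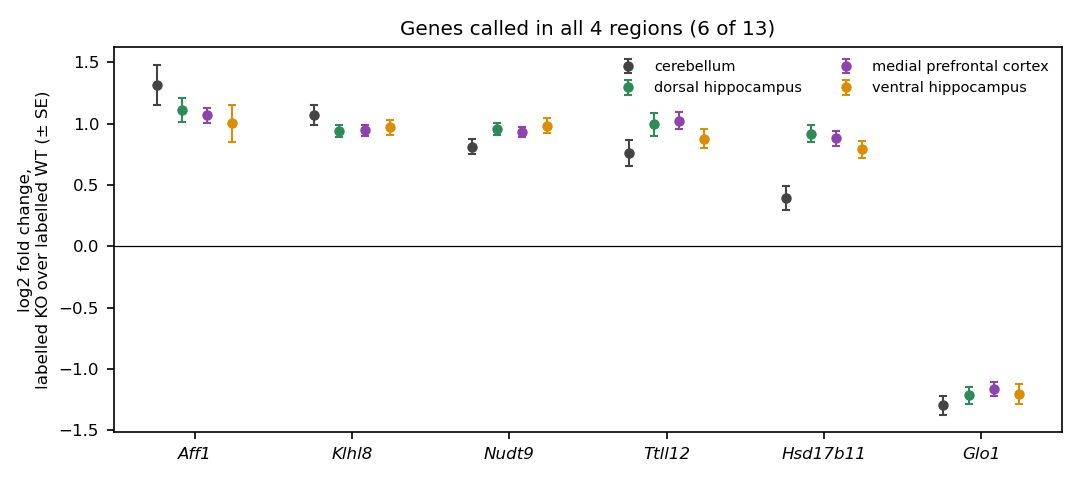
Log2 fold change of the libraries labelled KO over those labelled WT (vertical axis), with its standard error, for 6 of the genes called in all 4 regions, n = 6 libraries per label and region. Colours are regions, and the horizontal line marks no change. Glo1 lies between -1.30 and -1.17 and Klhl8 between 0.94 and 1.07.

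Aff1, Klhl8, Hsd17b11 and Nudt9 lie side by side on chromosome 5 between 103840240 and 104213245. Glo1 (chromosome 17, 30803910 to 30845845) lies within 1 Mb of 2 of the placeholder-named genes called in all regions. Ttll12 (chromosome 15, 83459291 to 83479358) has no other such gene within that distance. Glo1 overlaps Dnah8 on the opposite strand, and the strand setting of the counting is not stated. Around Cyp2e1 itself, 317 genes lie within 5 Mb, 105 of them were tested in all regions, and 11 were called in any region, Cyp2e1 included. Of all 16236 genes tested in every region, 1424, 17, 3 and 13 were called in exactly 1, 2, 3 and 4 regions, which is a similar share. Sprn, the gene of the shadow prion protein, was lower under the KO label in the dorsal hippocampus, at 150 against 196 CPM (log2 change -0.39, SE 0.05, adjusted p = 0.00396). In the cerebellum Nkx6-2 (log2 change -1.03), Th (tyrosine hydroxylase, -1.55), Mrgpre (-1.05) and Dhcr7 (-0.49) were lower and Cracr2b (0.93) was higher, each at an adjusted p of 0.0427 or 0.0428. Such values lie close to the threshold, as did 1405 of the 1422 cerebellar calls. As a positional list the genes within 5 Mb were not called by camera in any region (adjusted p from 0.552 to 0.797).

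In the cerebellum members of lists of myelin and of cholesterol synthesis genes were called, in libraries whose granule marker means also differed between the labels (1.00 against -1.01). Of 18 oligodendrocyte and myelin genes, 15 fell, including Opalin (15.0 against 31.5 CPM, log2 change -1.07, SE 0.20), Mag (200 against 378 CPM, -0.89, SE 0.21), Myrf, the myelin transcription factor (-0.74), and Ppp1r14a (-0.73). Adjusted over the list alone all 18 fell. Of 23 cholesterol synthesis genes 15 fell, including Insig1 (70.6 against 110 CPM, -0.64), and 1 rose. Adjusted over the list alone, 19 fell and 2 rose. The camera test called both lists lower (adjusted p = 1.44e-12 and 6.33e-08), and both calls were lost with an estimated correlation (adjusted p = 0.71 each). Within males 18 myelin and 19 cholesterol genes were called, and within females none (0 by edgeR, with 2 and 1 at an unadjusted p under 0.05, and 0 by DESeq2). The difference between the sexes was not called over all genes for any gene of these lists (0 by edgeR, 2 and 11 at an unadjusted p under 0.05, 0 and 1 by DESeq2). Adjusted over the list alone it was called for 0 myelin and 6 cholesterol genes. With the granule marker mean as a covariate no gene of either list was called for genotype (0 by edgeR, 17 and 14 at an unadjusted p under 0.05) or within males (0, 14 and 16). The 3 libraries with the lowest granule marker means all carried the WT label. Leaving them out kept 1 male WT library, so calls of that fit are not given for these lists. Of 40 monoamine and acetylcholine genes 12 fell, among them Th (5.34 against 13.0 CPM), Ache (acetylcholinesterase, 136 against 221 CPM, -0.76) and Htr2a (-1.48); camera adjusted p was 5.56e-09, and 0.71 with an estimated correlation. Adjusted over the list alone, 25 fell and 1 rose. Of 16 microglial genes 4 fell, among them Cx3cr1 (-0.57 on the log2 scale), Csf1r (-0.46) and Ctss (-0.47), and of 10 genes of oligodendrocyte precursors 3 fell (Olig2, Olig1 and Pdgfra), with camera adjusted p = 9.57e-05 and 0.000227 and adjusted p = 0.71 with an estimated correlation for each. In these lists 11 microglial and 8 precursor genes fell adjusted over the list alone. The clock genes Per2 (44.9 against 26.0 CPM, 0.81), Cry1 (0.90) and Nfil3 (0.48) were the 3 of 22 circadian genes that rose (11 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00017, and 0.71 with an estimated correlation). Of 40 xenobiotic metabolism genes 6 fell, among them Cyp2s1 (log2 change -1.07), Gstm5 (-0.51) and Sult4a1 (-0.54), without a call of the list (adjusted p = 0.395; 7 fell adjusted over the list alone).

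Among single cerebellar genes, Scara5, a ferritin receptor, was lower under the KO label at 0.551 ± 0.505 against 1.92 ± 0.841 CPM (SD, n = 6 each; adjusted p = 0.0181). Dnah8, an axonemal dynein that overlaps Glo1, fell from 4.79 ± 0.647 to 1.05 ± 0.426 CPM, and the stem cell marker Lgr5 from 13.6 ± 1.96 to 8.52 ± 1.12 CPM. The mean log2 level of 12 markers of cerebellar granule cells, relative to the region, was 1.00 ± 1.05 in the libraries labelled KO and -1.01 ± 1.61 in those labelled WT (SD, n = 6 each), with overlap between the labels (1.32 in male WT 1 and -0.577 in female KO 3). None of the 12 granule genes and none of the 12 Purkinje cell genes was called, over all genes or over the list alone. Their median log2 changes were 1.38 and 1.3, and camera called both lists higher (adjusted p = 0.000225 and 6.26e-05; adjusted p = 0.822 with an estimated correlation for each). Chn2, for example, averaged 560 against 190 CPM (adjusted p = 0.151) and Calb1 612 against 190 CPM (adjusted p = 0.0882). Lists of the cytosolic ribosome (3 of 74 fell, none over the list alone; adjusted p = 0.000427), amygdala and piriform cortex (3 of 10 fell, 5 over the list alone; 0.0124) and hypothalamus (2 of 8 fell, also over the list alone; 0.0169) were called lower by camera and lost their calls with an estimated correlation (adjusted p = 0.822, 0.71 and 0.71).

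Over all genes, 1422 of 17825 tested were called in the cerebellum, 433 higher and 989 lower under the KO label, and 1405 of these calls had an adjusted p between 0.04 and 0.05. The balance of directions varied. It was 95 higher and 427 lower with the replicate number as a block, 1728 and 2187 with DESeq2, and 2833 and 3407 with all 48 libraries in one model. Within females 6 genes were called and within males 3606, the latter being 10 when only male libraries were fitted, and 5, 7, 868, 1166 and 7452 without male KO 3, male WT 2, male KO 1, male WT 3 and male WT 1. At the same time no gene was called for a sex by genotype difference (0 by edgeR, with 2412 at an unadjusted p under 0.05, and 162 by DESeq2). The genotype count averaged over the sexes fell to 11 with the granule marker mean as a covariate and to 522 with the replicate number as a block. It rose to 3915 with DESeq2 and to 6240 with all 48 libraries in one model. The 3 libraries with the lowest granule marker means all carried the WT label (male WT 3 at -2.56, female WT 1 at -2.43 and male WT 2 at -1.87). Leaving them out kept 1 male WT library, so the count of that fit is given only with the dependence on processing. Leaving out 1 library gave 7 (male KO 3), 9 (female WT 1 or female WT 2), 10 (female WT 3), 12 (female KO 2 or male WT 2), 19 (female KO 1 or male KO 1), 35 (male WT 3), 703 (female KO 3) or 6400 calls (male WT 1).

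**Figure D3:**
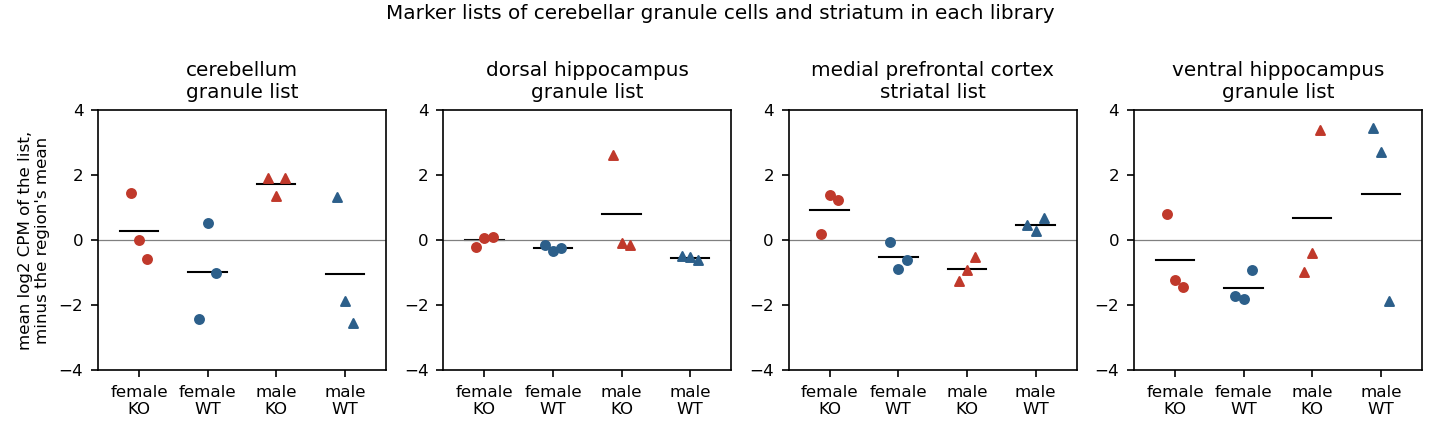
Mean log2 CPM of a marker list in each library minus the mean of its region (vertical axis), for cerebellar granule cell markers in 3 regions and striatal markers in the medial prefrontal cortex. Points are libraries (3 per group) and the bar is the group mean. Granule marker means run from -2.56 to 1.91 in the cerebellum and from -1.88 to 3.46 in the ventral hippocampus.

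In the dorsal hippocampus a few members of the lists of GABA, glutamate receptor, astrocyte and clock genes were called. Gabra4 (100 against 120 CPM, log2 change -0.25, SE 0.04) and Gabra5 (79.6 against 104 CPM, -0.39), subunits of the GABA-A receptor, were among the 3 of 22 GABA genes that fell. There were 5 that fell and 3 that rose adjusted over the list alone, and the list was not called by camera (adjusted p = 0.421). The metabotropic receptor gene Grm5 (198 against 234 CPM, -0.24) and the NMDA receptor gene Grin2b (321 against 414 CPM, -0.36) were the 2 of 32 glutamate receptor genes that fell. Adjusted over the list alone 9 fell and 2 rose, and camera called this list lower (adjusted p = 0.00276; adjusted p = 0.369 with an estimated correlation). Of 11 excitatory neuron genes Rasgrp1 fell (474 against 628 CPM, -0.40, adjusted p = 0.00905), 8 fell adjusted over the list alone, and camera adjusted p was 3.91e-09 (adjusted p = 0.684 with an estimated correlation). Of 16 astrocyte genes 2 rose, among them Gjb6 (connexin 30, 73.9 against 58.6 CPM, 0.34), 6 rose adjusted over the list alone, and camera adjusted p was 4.04e-05 (adjusted p = 0.71 with an estimated correlation). Cry1 (25.7 against 18.6 CPM, 0.47) and Per2 (49.0 against 35.0 CPM, 0.50) rose again among the circadian genes, where 4 rose adjusted over the list alone (camera adjusted p = 0.000317; adjusted p = 0.71 with an estimated correlation). Plin4, a lipid droplet coat protein induced by glucocorticoids, rose from 5.38 to 12.4 CPM (1.27, SE 0.26, adjusted p = 0.0440), the only one of its 23 tested list members called over all genes (6 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.000969; adjusted p = 0.71 with an estimated correlation).

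Other dorsal hippocampal genes that fell were Dcp1a, an mRNA decapping factor (18.9 ± 0.646 against 28.1 ± 2.49 CPM), Rgs14, a regulator of G protein signalling typical of area CA2 (40.6 ± 3.58 against 59.7 ± 10.4 CPM), and Ano3, an anoctamin (118 ± 5.99 against 153 ± 7.15 CPM), each as mean and SD with n = 6 per label. Chrm1, the muscarinic M1 receptor, also fell (169 against 208 CPM, adjusted p = 0.0440). Camera called 7 other lists here: ribosome lower (adjusted p = 3.91e-09; 1 of 73 fell, 5 over the list alone), nuclear oxidative phosphorylation lower (0.00125), dentate gyrus lower (0.000355; median log2 change -0.33), granule higher (0.000227; 0.79), meningeal fibroblast higher (0.000969), interferon and MHC higher (0.00577) and Purkinje higher (0.0155). The adjusted p with an estimated correlation was 0.822 for the oxidative phosphorylation, fibroblast and Purkinje lists and 0.71 for the other 4. The granule marker mean of male KO library 1 was 2.63 above the region's mean, while those of the other 11 lay between -0.623 and 0.104. In total 114 of 17402 genes were called, 32 higher and 82 lower, all with the same sign in both sexes; 10 were called within females and 326 within males, and no sex by genotype difference was called (0 by edgeR, 2253 at an unadjusted p under 0.05, 284 by DESeq2). The count was 191 without male KO 1, the library doubted here, and 36, 38, 56, 57 and 64 without female WT 3, male WT 1, female WT 2, male WT 3 and female WT 1. It was 25 in a model of all 48 libraries and 437 with DESeq2. The balance of directions also moved. It was 83 higher and 82 lower with the granule marker mean as a covariate (69 of the 114 shared), 668 and 438 without a low-count filter, and 129 and 308 with DESeq2. The share of mitochondrially encoded counts went with the label in opposite ways in the sexes here, at 3.84% to 4.24% (KO) against 2.72% to 3.09% (WT) in males and 2.74% to 3.65% against 3.81% to 4.17% in females, and its cause was not tested. Of 13 such genes 7 were called within males over all genes and 9 over the list alone, against 0 and 5 within females. A sex by genotype term was called over the list alone for 10 (median -0.672, 0 over all genes by edgeR, 10 at an unadjusted p under 0.05, 7 by DESeq2). The male count was 21 with only male libraries, 39 with all 48 libraries in one model and 1061 with DESeq2. Leaving out 1 library gave it 29 (male WT 1), 60 (male KO 3), 64 (male WT 3), 147 (female WT 3), 164 (female WT 1), 180 (female WT 2), 496 (male WT 2) or 726 (female KO 1).

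In the medial prefrontal cortex Plin4 rose from 3.98 to 10.4 CPM (log2 change 1.38, SE 0.20, adjusted p = 0.00435), and Slc2a1, the glucose transporter of the blood-brain barrier, from 88.2 to 110 CPM (0.33, SE 0.05, adjusted p = 0.00796). These were the 2 of 23 glucocorticoid response genes called over all genes, and 9 rose adjusted over the list alone. Tsc22d3 averaged 59.8 against 49.5 CPM (adjusted p = 0.0513) and Zbtb16 61.7 against 51.8 CPM (adjusted p = 0.0994). Camera called the list higher (adjusted p = 1.04e-06; adjusted p = 0.369 with an estimated correlation). Hmgb3 fell from 19.5 ± 2.96 to 12.3 ± 1.14 CPM, Dcp1a from 25.7 ± 1.5 to 18.5 ± 1.16 CPM and Rasl11b from 76.6 ± 8.86 to 61.6 ± 3.85 CPM (SD, n = 6 each). Among 52 nuclear oxidative phosphorylation genes none was called over all genes and 3 fell over the list alone, with Ndufa4 at 120 against 136 CPM (adjusted p = 0.0685) and Uqcrfs1 at 86.6 against 97.2 CPM (adjusted p = 0.116). Camera called that list lower (adjusted p = 4.06e-11; adjusted p = 0.71 with an estimated correlation). Within males 18 of the 52 were called over all genes and 37 over the list alone (median log2 change -0.195). Within females none was called either way (0 by edgeR, 2 at an unadjusted p under 0.05, 0 by DESeq2). With the striatal marker mean as a covariate 9 genes in total were called within males, so not all of the 18 can remain. For sex by genotype 2 were called over all genes and 28 adjusted over the list alone. Meningeal fibroblast (adjusted p = 1.76e-07; 7 rose over the list alone) and pericyte lists (0.0121; 1 rose over the list alone) were called higher without a member called over all genes, each with adjusted p = 0.71 with an estimated correlation. Ribosome (3.56e-08), ethanol and aldehyde metabolism (0.0121), cholesterol (0.013), GABA (0.0266) and excitatory neuron lists (0.0383) were called lower, also without such a member. The adjusted p with an estimated correlation was 0.71 for the ethanol and excitatory neuron lists and 0.822 for the other 3. In total 41 of 17067 genes were called, 29 higher and 12 lower. The striatal marker means of female KO libraries 2 and 3 were the highest. Leaving them out kept 1 female KO library, so the count of that fit is given only with the dependence on processing. Leaving out 1 library gave 21 (female WT 2), 24 (female KO 3), 26 (female KO 2 or male WT 2), 194 (male WT 1) or 244 (male KO 1), and DESeq2 gave 193.

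The genotype difference differed between the sexes for 274 genes in the medial prefrontal cortex, 136 with a positive and 138 with a negative sex by genotype term. The strongest were genes enriched in striatal neurons. Drd2, the dopamine D2 receptor, averaged 32.7 CPM in females labelled KO and 6.35 in females labelled WT, against 5.05 and 20.1 CPM in males (n = 3 each; difference of log2 changes 4.39, SE 0.56, adjusted p = 0.00324). Lrrc10b averaged 26.9 and 4.80 CPM in females against 3.66 and 19.7 CPM in males (4.95, SE 0.61, adjusted p = 0.00324). Nexn averaged 5.70 and 2.40 against 2.30 and 5.38 CPM (2.47, SE 0.31, adjusted p = 0.00324). All 14 genes of the striatal list had a called positive term, over all genes and over the list alone, with a median of 2.62. The median log2 change was 1.5 in females, where 10 were called, and -1.19 in males, where 12 were called. Their mean log2 level relative to the region was 0.939 ± 0.648 in females labelled KO, -0.524 ± 0.432 in females labelled WT, -0.898 ± 0.377 in males labelled KO and 0.481 ± 0.202 in males labelled WT (SD, n = 3 each). Within females 40 genes were called and within males 1114, against 22 and 34 with all 48 libraries in one model, 101 in females with DESeq2, and 399 in males with only male libraries. With the striatal marker mean as a covariate 7 were called in females and 9 in males. Leaving out 1 library gave 9 (female WT 3), 10 (female KO 2, female KO 3 or female WT 2), 14 (male WT 1), 26 (male WT 2) or 155 (female KO 1) in females, and 115 (male WT 2), 317 (male KO 2), 320 (male KO 3) or 328 (male WT 3) in males. No gene was called for the sex by genotype difference with the striatal marker mean as a covariate (0 by edgeR, with 915 at an unadjusted p under 0.05). Covariates shuffled within groups left 0 to 40 calls (median 0) in 20 draws. The loss of calls therefore does not show that they depended on striatal content. Leaving out female KO libraries 2 and 3 kept 1 female KO library, so the count of that fit is given only with the dependence on processing. Leaving out 1 library gave 59 (female WT 3), 67 (female KO 3), 70 (female WT 2), 93 (female KO 2), 94 (male WT 2 or male WT 3), 107 (male KO 3), 125 (male KO 2), 639 (female WT 1), 656 (male WT 1) or 800 calls (male KO 1).

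In the ventral hippocampus 13 of 17388 genes were called, 8 higher and 5 lower under the KO label, and these were the genes called in all 4 regions. Klhl8 stood at 75.5 ± 1.75 against 38.5 ± 2.97 CPM, Nudt9 at 88.4 ± 6.83 against 44.8 ± 2.57 CPM and Glo1 at 70.4 ± 5.26 against 162 ± 21.8 CPM (SD, n = 6 each). Camera called the glucocorticoid response list higher (adjusted p = 0.000227; adjusted p = 0.71 with an estimated correlation; 1 rose over the list alone), with Plin4 at 9.48 against 5.54 CPM and Tsc22d3 at 74.4 against 57 CPM (adjusted p = 0.878 and 1.00). It called lower the meningeal fibroblast list (1.09e-08; 3 fell over the list alone), with Col3a1 at 5.24 against 11.3 CPM, the pericyte list (0.000519; 4 fell over the list alone), with Acta2 at 20.0 against 40.6 CPM, and the interferon and MHC list (0.000969), with Cd74 at 6.16 against 11.8 CPM. With an estimated correlation the adjusted p of these 3 was 0.71, 0.71 and 0.735. Ribosome (0.000519), ventral hippocampal marker (0.00452) and ethanol and aldehyde lists (0.0333) were also called lower (adjusted p = 0.877, 0.71 and 0.71 with an estimated correlation). No member of these lists was called over all genes. Granule marker means of male WT 1, male KO 3 and male WT 2 stood 3.46, 3.40 and 2.71 above the region's mean, with those of the other 9 between -1.88 and 0.796. Within females 8 genes were called and within males 7, and no sex by genotype difference was called (0 by edgeR, 755 at an unadjusted p under 0.05, 1 by DESeq2). As in the dorsal hippocampus, the share of mitochondrially encoded counts went with the label in opposite ways in the sexes. It was 3.51% to 3.7% (KO) against 3.18% to 3.49% (WT) in males, and 3.66% to 4.01% against 3.98% to 4.29% in females. For 5 of 13 such genes a sex by genotype term was called over the list alone (median -0.339).

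Whether the genotype difference varied between regions was tested over all 48 libraries. Of 19183 genes 1495 were called. Lamp5, a lysosomal membrane protein of cortical neurons, had log2 changes of -2.91 in the cerebellum, -0.25 in the dorsal hippocampus, -0.16 in the medial prefrontal cortex and 0.16 in the ventral hippocampus (adjusted p = 0.000995). The orexin receptor gene Hcrtr2 had -1.76, 0.24, 0.24 and 0.08 (adjusted p = 0.000995), and Fgfr3, an astrocyte growth factor receptor, -0.44, 0.22, 0.03 and 0.16 (adjusted p = 0.00159). Limk1, Tubb3 and Crtac1 had -1.10, -0.98 and -1.28 in the cerebellum and between -0.15 and 0.10 elsewhere (adjusted p = 0.00162, 0.00223 and 0.00223). Lamp5 in the cerebellum averaged 7.03 ± 6.71 against 63.7 ± 80.5 CPM (SD, n = 6 each), so its spread exceeded its mean under the WT label. Without the doubted libraries the test called 30, and without the cerebellum none (0 by edgeR, with 496 of 18513 at an unadjusted p under 0.05). Leaving out 1 library gave 398 (female KO 1), 412 (male WT 2), 546 (male KO 3), 669 (female WT 1), 750 (female WT 3), 889 (male WT 3), 891 (male KO 1) or 3672 calls (male WT 1) for cerebellar libraries, and 2336 without male KO 3 of the ventral hippocampus.

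Genes on the X or Y chromosome were 7 of 7, 9 of 10, 11 of 18 and 6 of 6 of those called between the sexes in cerebellum, dorsal hippocampus, medial prefrontal cortex and ventral hippocampus. Xist averaged between 405 and 614 CPM in the female groups and at most 0.157 CPM in the male groups. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were higher in males in all 4 regions, and so were all 4 adjusted over the list alone. Of 8 genes known to escape X inactivation, 2, 4, 6 and 1 were higher in females in cerebellum, dorsal hippocampus, medial prefrontal cortex and ventral hippocampus (6, 7, 8 and 6 adjusted over the list alone). Eif2s3x had log2 differences of 0.55, 0.58, 0.58 and 0.43, of which the last was not called (adjusted p = 0.145). On autosomes, the thyroid hormone receptor gene Thra was lower in females in the dorsal hippocampus (536 ± 15.2 against 652 ± 91.8 CPM, SD, n = 6 each; log2 difference -0.27, adjusted p = 0.0242), and it overlaps Nr1d1. In the medial prefrontal cortex Aebp1 (9.98 ± 1.59 against 21.7 ± 10.8 CPM), Ptgds, prostaglandin D2 synthase (291 ± 43.1 against 546 ± 236 CPM), Txnip (10.9 ± 1.08 against 15.8 ± 3.05 CPM) and the laminin gene Lamb2 (30.7 ± 1.22 against 41.3 ± 7.71 CPM) were lower in females than in males (n = 6 each; adjusted p = 0.0158, 0.0213, 0.0182 and 0.0182). These counts were not stable. They were 73, 30, 83 and 508 with DESeq2, 2040, 9 and 1182 with all 48 libraries in one model in cerebellum, prefrontal cortex and ventral hippocampus, and 474, 336 and 734 without a low-count filter in dorsal hippocampus, prefrontal cortex and ventral hippocampus. Without male WT 3 the cerebellar count was 83 and the ventral hippocampal count 1091, without male KO 2 the ventral hippocampal count was 120, and without male KO 3 the prefrontal count was 56.

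Dorsal and ventral hippocampus were compared over 24 libraries, averaged over sex and genotype label. Pou4f1, a transcription factor of the medial habenula, was higher in the dorsal libraries and averaged 12.9 against 0.701 CPM (log2 difference 5.16, SE 0.60, adjusted p = 3.3e-05), Gpr151 13.8 against 0.744 CPM (4.08, SE 0.51), Chrnb3 8.63 against 0.949 CPM (3.24, SE 0.29) and Chrna3 13.9 against 1.56 CPM (3.14, SE 0.42), the last 2 encoding nicotinic receptor subunits. The midbrain and diencephalic factors Sox14, Dmbx1, Pax7 and Gata3 differed by 4.72, 4.44, 4.20 and 3.26 on the log2 scale. Dio3, the thyroid hormone-inactivating deiodinase, was higher in the ventral libraries (4.73 against 0.410 CPM; -3.55, SE 0.26, adjusted p = 1.65e-07), as were Dsc3 (-2.52), Krt2 (-2.42), Fermt1 (-1.99), Col23a1 (-1.84), Ano2 (-1.83) and Dcn (-1.75). Cbln3 was the only one of 12 cerebellar granule genes called (203 against 42.1 CPM; -4.21, SE 1.40, adjusted p = 0.0428), and none was called over the list alone. The ventral libraries male WT 1, male KO 3 and male WT 2 stand apart in these markers (3.46, 3.40 and 2.71 above the region's mean), so this need not be a difference between the regions. Of 9 dorsal markers 3 were higher dorsally (Lct 2.43, Dsp 1.11, Pantr1 0.58) and 2 ventrally (Ccn3 -0.90, Gpc3 -0.52). Of 12 ventral markers 5 were higher ventrally (Trhr -1.16, Dcn, Nr2f2 -1.02, Grp -0.76, Efnb2 -0.19) and 2 dorsally (Htr2c 0.86, Cadm2 0.43). Adjusted over each list alone, 5 and 7 were called. The median log2 difference was -0.0693 over the dorsal list and 0.0823 over the ventral list, so neither list as a whole followed its region. All 10 ependymal genes (median log2 difference 1.61), all 18 oligodendrocyte genes (0.688) and 7 of 12 thalamic genes (0.455) were higher dorsally. In contrast 13 of 14 meningeal fibroblast genes (-0.968) and 5 of 6 border macrophage genes (-0.866) were higher ventrally. Adjusted over the list alone, 10 ependymal, 18 oligodendrocyte, 9 thalamic, 13 fibroblast and 6 macrophage genes were called. Whether the dissected pieces differed in their share of neighbouring tissue was not tested. In total 3166 of 18184 genes were called, 1709 higher dorsally and 1457 ventrally, 412 of them by more than 2-fold.

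Across the 4 regions camera called 39 of 182 list tests, 14 higher and 25 lower under the KO label. With an estimated correlation it called none, and neither did the directional fry test (0 of 182 each), while the fry test for change in either direction called 62. At the preset correlation, most other splits of the same libraries gave at least as many list calls, as given below. The count of called lists therefore does not separate the labels from other groupings. Lists of mitochondrially encoded genes (adjusted p from 0.0652 to 0.84), immediate early genes (0.407 to 0.845), NRF2 targets (0.0649 to 0.789), ER stress (0.649 to 0.968), heat shock chaperones (0.371 to 0.876) and inflammatory cytokines (0.31 to 0.876) were not called by camera in any region for genotype averaged over the sexes.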

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

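The tests of the 13 shared genes, of the Cyp2e1 direction, of library size and with the marker covariate were chosen after the result was seen, while the splits of the samples were not. The 2 tests of direction along marker slopes were set beforehand, but their exact enumeration replaced random rearrangements after the cerebellar p of these had been seen to lie at the 0.05 threshold, so that p is borderline.

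Cyp2e1 was higher in all 24 libraries labelled KO than in any labelled WT. Single libraries swapped between the labels were argued against, since 0 libraries labelled KO lay at or below the highest labelled WT. Liver RNA was argued against as well, since the other liver genes, Alb included, had a KO to WT ratio of at most 1.13 in any region. Genotype labels exchanged for every library could explain the counts (at least 34 in each labelled KO), and so could a transcript of the exons that remain in the targeted allele with little Cyp2e1 in the other line (at most 8 in each labelled WT). These 2 cannot be told apart without counts per exon.

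The 13 genes called with the same sign in all 4 regions include Klhl8, Nudt9, Aff1, Hsd17b11 and Glo1. An unequal share of tissue rich in granule markers, or of striatum, was argued against as the whole source for 10 genes. These were still called in all regions with the marker covariate. Sizes still moved with it for some in the cerebellum, where Aff1 went from 1.319 to 0.913 (0.692 of its size) and Hsd17b11 from 0.394 to 0.637. The other 3 lost a call because standard errors widened, while the fold kept at least 0.861 of its size; among them, chosen after its values were seen, Gm26881 in the cerebellum went from 3.26 (SE 0.421) to 2.81 (SE 0.572). Of the other 12 genes 0 lie within 5 Mb of Cyp2e1, and passenger DNA next to it was argued against for those on other chromosomes. The placeholder-named E230029C05Rik lies on chromosome 7 too, at 89.63 Mb against 140.34 Mb for Cyp2e1. For that gene the 5 Mb window cannot exclude a longer segment. A few chromosome segments that differ between the 2 mouse lines may explain part of the 13 genes. Of these, 7 have another within 1 Mb, against a mean of 0.243 and a highest of 4 in 10000 random draws (permutation p = 1e-04, the smallest the draws can give). An effect of the Cyp2e1 allele itself stays open as untested.

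The genotype difference itself differed between the sexes for 274 genes in the medial prefrontal cortex, by 4.95 for Lrrc10b, 2.47 for Nexn and 4.39 for Drd2 on the log2 scale, and 1422 genes were called for genotype in the cerebellum. In the cerebellum 94.7% of the called genes lay in the direction of their slope on the granule marker mean within groups (median 43.2% and highest 96.8% over 1296 rearrangements, exact permutation p = 0.0432). An unequal share of tissue rich in granule markers may therefore contribute, with a median predicted share of the change of 0.393. These values do not single out the granule layer, since median log2 changes of Purkinje and granule markers were alike (0.926 and 1.09 in females, 1.84 and 1.67 in males). For striatum in the prefrontal pieces the figure was 74.2% of 260 genes (exact permutation p = 0.141), so it cannot be told apart from a sex-specific effect, because 183 rearrangements gave as much. With the covariates the median absolute log2 change went from 0.557 ± 0.582 to 0.322 ± 0.539 in the cerebellum and from 0.892 ± 1.3 to 0.503 ± 0.79 in the prefrontal cortex, and calls ended as changes shrank; covariates shuffled between libraries left 5 to 6509 (median 6) and 0 to 40 (median 0) calls in 20 draws each, so the loss of calls by itself is no evidence for either source. A difference in library size between the labels was argued against in the cerebellum (ratio 1.08) and within each sex of the prefrontal cortex (ratio at most 1.02), and a biological effect of genotype stays open as untested.

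The genotype difference varied between regions for 1495 genes by the F test over regions, including Lamp5 (adjusted p = 0.000995), Hcrtr2 (0.000995), Fgfr3 (0.00159), Limk1 (0.00162), Tubb3 (0.00223) and Crtac1 (0.00223). It called 30 without the doubted libraries and 0 without the cerebellum (edgeR, 496 at an unadjusted p under 0.05), so the calls rest on the cerebellar libraries.

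Splits of the same libraries into groups of the same sizes were fitted, 100 per result with the real one included. The share of splits as large as the real one was under 0.05 for genotype in the cerebellum (2 splits as large, 1422 calls, highest other 4303), the dorsal hippocampus (2, 114, highest other 306) and the medial prefrontal cortex (4, 41, highest other 935), for sex by genotype in the prefrontal cortex (2, 274, highest other 935) and for the difference between regions (3, 1495, highest other 2792). It was also under 0.05 for dorsal against ventral (1, 3166, highest other 9) and for sex in cerebellum (1, 7, highest other 1), dorsal hippocampus (1, 10, highest other 3), prefrontal cortex (2, 18, highest other 274) and ventral hippocampus (3, 6, highest other 119). Chance is argued against where no other split reached the real count. Elsewhere, apart from sex in the prefrontal cortex (below), another split gave more calls, so the count alone cannot exclude chance. The share was higher for genotype in the ventral hippocampus (11, 13, highest other 1415) and the gene lists (76, 39, highest other 69). The splits ignored the replicate number, although the immediate early genes were lowest in replicate 1 in 16 of 16 groups. For sex by genotype in cerebellum, dorsal and ventral hippocampus the real count is 0, so all 100 splits give as many and decide nothing (highest others 1943, 306 and 1340). Splits with several times the real count point to a structure of the samples, and what it is was not tested. The split with 274 for sex in the prefrontal cortex exchanges the sexes in 1 genotype only, so it is the sex by genotype grouping, and the highest of the remaining splits gave 16. Within a sex, 10 splits are too few for a share under 0.05. In females the real counts and highest others were 6 and 0, 10 and 2, 40 and 0, and 8 and 0 in cerebellum, dorsal hippocampus, prefrontal cortex and ventral hippocampus, and in males 3606 and 0, 326 and 16, 1114 and 27, and 7 and 2479.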

How the results depend on the processing

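The marker covariate, the removal of doubted libraries and the test without the cerebellum were chosen after seeing the data. Size factors of the DESeq2 type left each count of calls within 1.5 times its value, and no named gene reversed under any alternative (6842 values on the same side of the threshold, 1026 no longer past it, 235 newly past it). The counts that moved further follow, and the cause was not tested.

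With the replicate block, genotype calls in the cerebellum were 522 (484 shared) and sex by genotype 4. Across regions a library's own number was the best match in 38 of 72 comparisons, where chance gives 24, a hint from the data, not the design, that numbers are shared. The median correlation between regions was also higher for the same number in 6 of 6 comparisons. Within regions 21 of 72 pairs correlated above 0.1, but these join different groups and cannot show whether regions share animals. No pairs were assumed, since the labels state none, and the splits ignored the number. If numbers mark animals, the test between regions and dorsal against ventral treated libraries of the same animal as independent. With the marker covariate the counts of calls were 11 in cerebellum and 10 in its males, 173 in dorsal hippocampal males, and in the prefrontal cortex 7 in females, 9 in males, 0 for sex by genotype and 10 for sex. Without the doubted libraries they were 13 in cerebellum, 18 in its males, 1 for sex by genotype and 12 for sex, 191 in dorsal hippocampus, 15 in prefrontal cortex, 7 in its females, 0 for sex by genotype and 8 for sex, and 30 for the difference between regions; this left 1 library in 3 groups, assumed to vary like the others. Without the cerebellum that difference gave 0.

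With DESeq2 the counts were 3915 (1387 shared), 12 in females, 162 for sex by genotype and 73 for sex in cerebellum; 437, 23 in females, 1061 in males, 284 and 30 in dorsal hippocampus; 193, 101 in females, 621 and 83 in prefrontal cortex; and 13 in females, 14 in males, 1 and 508 in ventral hippocampus. With all 48 libraries in one model they were 6240, 14, 7223, 1054 and 2040 in cerebellum (genotype, females, males, sex by genotype, sex), 25, 39 in males and 11 for sex by genotype in dorsal hippocampus, 19, 22, 34, 43 and 9 in prefrontal cortex, and 13 in females, 14 in males and 1182 for sex in ventral hippocampus. With only one sex they were 2 and 10 in cerebellum, and in males 21, 399 and 0 in dorsal hippocampus, prefrontal cortex and ventral hippocampus. Without a low-count filter they were 35 for sex by genotype in cerebellum, 1106, 160, 1675, 546 and 474 in dorsal hippocampus, 562, 261, 1744, 1078 and 336 in prefrontal cortex, and 16 in males and 734 for sex in ventral hippocampus. The stricter filter gave 25 in prefrontal females. Camera with an estimated correlation and directional fry each called 0 lists.

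Leaving out each library gave 7 (male KO 3) to 6400 (male WT 1) genotype calls in cerebellum, 3 (female WT 3) to 6 in females, 5 (male KO 3) to 7452 (male WT 1) in males, 7 also without male WT 2, 868 without male KO 1 and 1166 without male WT 3. There, sex by genotype gave 0 to 6 (female KO 1; 1 without male WT 3) and sex 7 to 83 (male WT 3). In dorsal hippocampus it gave 36 to 191, 8 to 12 in females, 7 to 11 for sex, 0 to 0 for sex by genotype, and in males 29 (male WT 1) to 726 (female KO 1), with 60, 64, 147, 164, 180 and 496 without male KO 3, male WT 3, female WT 3, female WT 1, female WT 2 and male WT 2. In prefrontal cortex it gave 21 to 244, 59 to 800 for sex by genotype, 13 to 56 for sex (male KO 3), in males 115 (male WT 2) to 1540 (male KO 1), with 317, 320 and 328 without male KO 2, male KO 3 and male WT 3, and in females 9 (female WT 3) to 155 (female KO 1), with 10, 10, 10, 14 and 26 without female KO 2, female KO 3, female WT 2, male WT 1 and male WT 2. In ventral hippocampus it gave 10 to 12, 6 to 9 in females, 5 to 8 in males, 0 to 0 for sex by genotype and 6 to 1091 for sex (male WT 3; 120 without male KO 2). Lists gave 37 to 47, the difference between regions 398 to 3672, and dorsal against ventral 2360 to 4117.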

Other observations

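Each test in this part was chosen after the result was seen.

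Y-linked genes differed between the genotype labels in males. Eif2s3y averaged 41.9 ± 4.92 against 22.5 ± 7.24 CPM in cerebellum, 39.2 ± 5.36 against 22.8 ± 2.89 in dorsal hippocampus, 42.6 ± 5.92 against 25.9 ± 5.72 in medial prefrontal cortex and 37.8 ± 5.90 against 26.5 ± 2.44 in ventral hippocampus (KO against WT, SD, n = 3 each). It was called in 3 of these regions, and the adjusted p by edgeR was 0.0348, 0.0309, 0.021 and 0.854. Kdm5d was called in 2, with log2 changes of 0.67, 0.66, 0.78 and 0.76. Every male library labelled KO lay above every male library labelled WT for both genes in all 4 regions. For 1 gene in 1 region, chance gives no overlap in either direction in 10% of splits of 3 against 3. Both genes were picked after their values were seen and regions may share animals, so this figure does not measure the joint pattern. Ddx3y and Uty were not called in any region.

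The mean of the immediate early genes, which include Fos and Arc, was lowest in replicate 1 in 16 of 16 groups (one-sided exact binomial p = 2.32e-08). It averaged -0.677 ± 0.288, 0.275 ± 0.22 and 0.402 ± 0.393 in replicates 1, 2 and 3 on the log2 scale (SD, n = 16 each). The groups are not independent if regions came from the same animals. With the regions averaged it was lowest in replicate 1 in 4 of 4 groups of sex and genotype (one-sided exact binomial p = 0.0123). Both p-values treat replicate 1 and this list as named in advance, although they were picked after their values were seen, so both are too small.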
